A study of Mus musculus with 18 samples.

How the data were processed

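RNA was sequenced from GL261 cells, a mouse glioma line that here carries green fluorescent protein (GFP), and from the tumours these cells formed in C57BL/6 wild-type (WT) or Pfp/Rag2-/- mice. Per the labels, tumours of symptomatic mice, 6 of each host, were digested with collagenase to single cells. Cells were then sorted into a GFP+ tumour fraction and a GFP- non-tumour fraction. The sorted cells were compared with unsorted bulk cells that hold both populations and with the cultured GFP+ cells used for the injections. RNA was isolated with NucleoSpin columns, libraries were made with the NEBNext mRNA isolation and directional RNA kits, and they were read on a NextSeq 500. There were 18 libraries in 6 groups of 3. The labels call them triplicates and do not say whether a library came from 1 mouse or from a pool.

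The deposited values are a signal, a normalized count per gene and library that the authors made by dividing whole read counts by 1 size factor per library. The submitters' processing notes name STAR 2.5.2b, DESeq2 and the GRCm38 build. The read counter and the annotation release are not given in the sources used here. In every column 100.0% of the values were whole multiples of 1 step, within 0.05 reads, so the read counts could be recovered. The step, the value of 1 read, lay between 0.871 and 1.54. The analysis plan had foreseen raw counts as a fallback. The table held the normalized signal, so the plan for normalized values was followed, and the recovered reads served the count-based alternatives. Recovered totals were 19172814 to 21141662 reads per library. Size factors were 0.649 to 0.761 in the GFP- libraries and 1.04 to 1.15 in all others. The table held 48795 genes, of which 48349 had a name in GENCODE vM21, the source of the coordinates, and 32595 had a read in at least 1 library.

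Each comparison was fitted to the libraries of its groups alone. Genes with a normalized count of at least 10 in at least 3 of the libraries fitted were kept, and log2 of the normalized count plus 1 was tested with limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3, two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The difference between sorted and unsorted host effects was tested as an interaction in 1 fit of 12 libraries. The 40 gene lists, the filter, the tests and the comparisons were fixed before the data were examined, and 6 list entries were not in the table. Lists with at least 3 measured members were tested with camera in limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. The same tests were repeated with an estimated correlation, and with fry, which asks whether the genes of a list move on balance in 1 direction. Counts of list members refer to adjustment over all genes tested. Counts adjusted over the list alone stand beside them.

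The rule for named genes was also fixed before the data were examined. It takes the 6 highest and 6 lowest log2 differences in each host comparison, and the 4 highest and 4 lowest in the others. These are taken among called genes whose groups do not overlap, with a mean of at least 100 in the higher group and a proper gene symbol. It adds up to 2 highest and 2 lowest called members of each list described, any list member given with its value, and Prf1 and Rag2. Chance alone gives groups that do not overlap in 10% of genes at 3 against 3. Where all libraries of a group were at 0, the fold is given as a lower bound against a floor of 3 reads per library. Such floors cover counting error only. For 3 genes picked in this way or for the text the single values are not reported here, and the genes stay in the counts and list tests.

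Carry-over of RNA from other cells into the sorted GFP+ libraries was estimated from 4 lists, for macrophages and microglia, T cells, endothelium and the oligodendrocyte lineage. For each library this was the median ratio, in percent, of a marker's normalized count to its mean in the GFP- libraries. Markers needed a GFP- mean of at least 50 and a cultured level under 10% of it. Hosts were compared with an exact two-sided permutation test computed in R, whose smallest possible p at 3 against 3 is 0.10. In an alternative chosen after the data were seen, the larger of the macrophage and T cell shares of each library, times the GFP- mean, was subtracted from each gene. The endothelial and oligodendrocyte shares were left out of that subtraction after their size had been seen.

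Other alternatives were log2 of the value plus 10, no filter, a filter at 50, quantile normalization, TMM factors, robust eBayes, all 18 libraries in 1 fit, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on recovered reads, a replicate block, and leaving out each library in turn. With a library left out, the filter of 3 libraries drops genes found only in the reduced group, so a version with the gene set kept was added after seeing the data. Leaving out both GFP+ libraries numbered 1 was also added then. Replicate numbers were treated as pairs only where libraries of the same number stayed correlated across genes, above 0.1 for each number, after the group means were removed. Between sorted GFP+ cells of both hosts these correlations were 0.616, 0.483 and 0.102. In the other comparisons the lowest lay between -0.41 and 0.068, so the block is an alternative there.

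The tests were checked on simulated data with known changes at the same depth and spread. Between sorted GFP+ cells of both hosts, 72.3% of 65 genes changed 2-fold were recovered, with 7 unchanged genes called among 14862 tested. Between GFP- and GFP+ cells, where replicates differed most, 8.96% of 67 genes changed 2-fold and 51.6% of 62 genes changed 4-fold were recovered. With carry-over of 2% put in, the macrophage markers returned 2.06%, the T cell markers 2.28%, the endothelial markers 2.85% and the oligodendrocyte markers 3.68%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the comparisons.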

Results

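The 18 libraries hold the messenger RNA of GL261 GFP glioma cells and of the tumours they formed in 2 kinds of host. WT hosts have a working immune system. Pfp/Rag2-/- hosts lack perforin, the pore-forming protein of killer lymphocytes, and Rag2, without which mature T and B cells do not form. The 6 groups, with 3 libraries each, are sorted GFP+ and unsorted cells from tumours of each host, sorted GFP- cells from WT tumours, and the cultured GFP+ cells. All levels below are normalized counts, given as mean ± SD with n = 3 per group, and log2 differences carry their standard error (SE). Ratios to a group with 1 to 3 reads are given with an exact Clopper-Pearson 95% interval (scipy 1.17.1), which covers counting error only. The p-values measure only the spread between these libraries, because the labels do not say whether a library is 1 mouse or a pool. Pearson's r across genes between replicates was 0.968 to 0.994, and the first principal component, with 62.1% of the variance, set the GFP- cells apart from all other libraries.

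Prf1, the perforin gene removed from the Pfp/Rag2-/- host (ENSMUSG00000037202, chromosome 10, 61297833 to 61304680), was at 115.7 ± 21.03 in unsorted WT tumours and at 12.31 ± 4.694 in unsorted Pfp/Rag2-/- tumours. The log2 difference was 3.19 (SE 0.33, adjusted p = 0.000861; 0.0573 with all 18 libraries in 1 fit). Its reads were 118, 110 and 160 in the WT libraries and 8, 15 and 18 in the Pfp/Rag2-/- libraries. In GFP- cells from WT tumours Prf1 stood at 2831 ± 816.8. Sorted GFP+ cells held 123, 5 and 11 reads in WT and 128, 6 and 1 in Pfp/Rag2-/- libraries 1, 2 and 3, a difference that was not called (log2 0.79, SE 1.68, adjusted p = 0.753), and cultured cells held 0, 1 and 0. Rag2 (ENSMUSG00000032864, chromosome 2, 101624718 to 101632529) had no read in any of the 9 libraries from WT hosts. It had 5, 7 and 4 reads in unsorted Pfp/Rag2-/- tumours, 5, 0 and 0 in Pfp/Rag2-/- GFP+ cells and 0, 1 and 0 in culture. Unsorted Pfp/Rag2-/- tumours were at least 1.78-fold higher for Rag2 than the floor of 3 reads in WT tumours. Gene counts cover the whole gene, so reads from parts outside a deletion cannot be told from intact transcripts, and the counts check the labels only in part. Pfp/Rag2-/- GFP+ library 1 held about as many Prf1 reads (128) as WT library 1 (123). It also held more NK cell RNA (17.6% against 4.85% of the GFP- level), little Cd3e (0.9132 against 33.52) and 5 Rag2 reads, which run with its label, so RNA of another mouse is neither shown nor excluded.

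Sorted GFP+ cells from WT hosts were compared with sorted GFP+ cells from Pfp/Rag2-/- hosts to ask what tumour cells express after growth under a complete immune system. Genes of antigen presentation and of the interferon-gamma response were higher in the WT hosts. Of 22 measured genes of MHC class I presentation, which shows peptides to killer T cells, 20 were higher and 0 lower (20 and 0 adjusted over the list alone), with a median log2 difference of 1.38 (adjusted p = 5.7e-16, and adjusted p = 0.589 with an estimated correlation). Psmb9, an immunoproteasome subunit, was 5.87-fold higher, at 3686 ± 113.2 against 632 ± 94.37 (log2 2.55, SE 0.10, adjusted p = 3.57e-05). Nlrc5, the transactivator of class I genes (ENSMUSG00000074151, chromosome 8, 94434356 to 94527272), was at 8072 ± 497.5 against 1861 ± 223.9 (log2 2.12, SE 0.09, adjusted p = 3.57e-05). B2m, the invariant class I chain (ENSMUSG00000060802, chromosome 2, 122147686 to 122153083), was at 30780 ± 2237 against 13940 ± 2470 (log2 1.16, SE 0.13, adjusted p = 0.00134). Of 29 genes of the interferon-gamma response, 26 were higher and 0 lower (28 and 0 adjusted over the list alone), with a median of 2.77 (adjusted p = 9.73e-21, and adjusted p = 0.589 with an estimated correlation). Gbp2, a guanylate-binding protein induced by interferon, was at 15770 ± 3072 against 1298 ± 231.5, and Irf1, a transcription factor of the same response, at 11320 ± 3664 against 1556 ± 162.3.

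MHC class II genes, which present peptides to helper T cells, were also higher in GFP+ cells of WT hosts, with 6 of 10 measured members called higher and 0 lower (8 and 0 adjusted over the list alone). Their median log2 difference was 3.80 (adjusted p = 0.000487, and adjusted p = 0.92 with an estimated correlation, 0.0515 with fry). Ciita, the transactivator of class II genes (ENSMUSG00000022504, chromosome 16, 10480059 to 10528418), was at 1298 ± 225.5 against 44.25 ± 36.09 (log2 5.11, SE 0.49, adjusted p = 0.000722). Cd74, the invariant chain, was at 15790 ± 3041 against 2311 ± 3372 (log2 4.06, SE 1.04, adjusted p = 0.0257). Pfp/Rag2-/- library 1 held 6204 of Cd74 and libraries 2 and 3 held 399.5 and 329.7. Cd74 did not pass with edgeR (adjusted p = 0.0982), DESeq2 (0.0712) or robust eBayes (0.0742), nor without WT library 1 (0.074) or 2 (0.0799) or Pfp/Rag2-/- library 2 (0.0905) or 3 (0.0858). Markers of macrophages and microglia, cells that express class II genes, stood in the GFP+ libraries at 1.52% ± 0.887 of their GFP- level in WT and 1.15% ± 1.2 in Pfp/Rag2-/- hosts (22 markers; exact permutation p = 0.6, where 0.10 is the smallest possible). Among WT libraries 1, 2 and 3 this share was 2.45%, 0.687% and 1.41%, and among Pfp/Rag2-/- libraries 2.54%, 0.466% and 0.453%. T cell markers stood at 1.25% ± 1.51 and 0.407% ± 0.578, or 1.99% and 1.39% with counts summed over markers (23 markers; exact permutation p = 0.5 each without pairing). By the median ratio they were higher in WT for each replicate number, treated as pairs here (2.98% against 1.07%, 0.216% against 0.0659% and 0.548% against 0.08%).

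**Figure D1:**
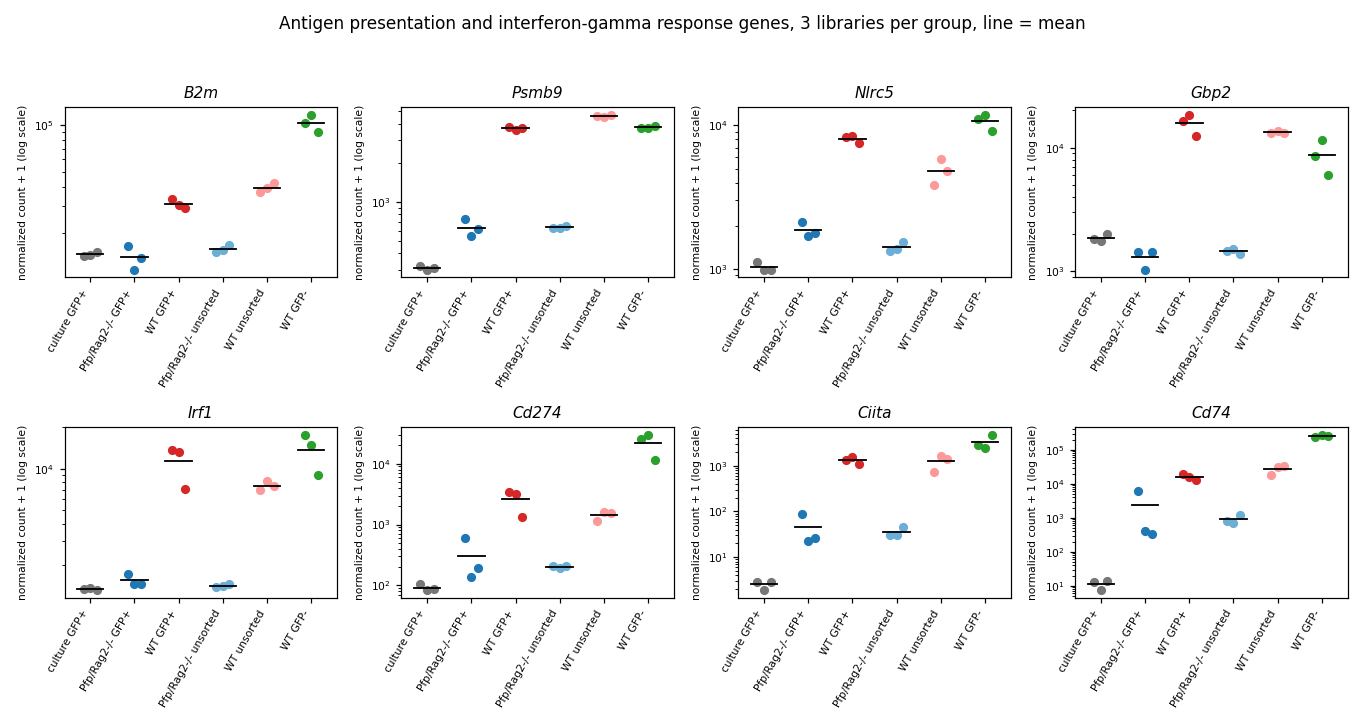
Normalized count plus 1 (log axis) of 8 genes of antigen presentation and the interferon-gamma response in each library of the 6 groups. Points are libraries and lines are group means. The Psmb9 mean is 3686 in GFP+ cells of WT hosts and 632 in GFP+ cells of Pfp/Rag2-/- hosts.

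Of 31 inhibitory ligands and immune evasion genes, 10 were higher and 2 lower in GFP+ cells of WT hosts (10 and 3 adjusted over the list alone). The median was 0.68 (adjusted p = 0.00509, and adjusted p = 0.92 with an estimated correlation, 0.0861 with fry). Cd274, which encodes the checkpoint ligand PD-L1 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095), was at 2662 ± 1160 against 309.5 ± 250.2 (log2 3.28, SE 0.59, adjusted p = 0.00758). Arg1, an enzyme that breaks down arginine, was at 902 ± 681.9 against 11.61 ± 5.84. The 2 lower genes were Tgfb2 (log2 -0.95, adjusted p = 0.0179) and Lgals9 (log2 -0.27, adjusted p = 0.0475). Tgfb2 did not pass without WT library 1 (adjusted p = 0.0525) or Pfp/Rag2-/- library 1 (0.0527) or 3 (0.0682), and Lgals9 did not pass without WT library 1 (0.114) or 2 (0.143) or Pfp/Rag2-/- library 1 (0.116) or 3 (0.148). Of 6 measured ligands of the killer-cell receptors NKG2D and DNAM-1, 3 were higher and 0 lower (4 and 0 adjusted over the list alone, median 0.29, adjusted p = 0.0119, and adjusted p = 0.589 with an estimated correlation), among them Raet1d (log2 0.83, SE 0.11) and Pvr (log2 0.78, SE 0.12). Complement genes were higher in 7 of 16 and lower in 1 (8 and 1 adjusted over the list alone). The median was 1.11 (adjusted p = 0.000146, and adjusted p = 0.83 with an estimated correlation). The inhibitor Serping1 was at 898.3 ± 75.95 against 39.09 ± 21.83. Of 16 chemokines 5 were higher and 0 lower (5 and 0 adjusted over the list alone). The median was 0.57 (adjusted p = 0.0288, and adjusted p = 0.92 with an estimated correlation). Cxcl10, which attracts T cells, was at 7021 ± 3313 against 1128 ± 177.9. The chemokine list did not pass with carry-over subtracted (median 0.46, adjusted p = 0.251), with fry (0.245), or without WT library 1 (0.128) or Pfp/Rag2-/- library 2 (0.0837) or 3 (0.153).

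Type I interferon-stimulated genes went both ways and did not pass the list test. Of 30 measured, 7 were higher and 8 lower in GFP+ cells of WT hosts (8 and 10 adjusted over the list alone). The median was -0.09 (adjusted p = 0.476). Oas2, an antiviral enzyme, was lower at 408.6 ± 18.73 against 2310 ± 434.6 (log2 -2.48, SE 0.14, adjusted p = 9.74e-05), as were Irf7 (log2 -1.07, SE 0.20) and Ifi27l2a (log2 -1.14, SE 0.15). Stat2 (log2 1.47, SE 0.13) and Parp14 (log2 1.15, SE 0.20) were higher. Isg15 (log2 -0.12), Ifit3 (-0.04), Mx1 (-0.04) and Rsad2 (-0.25) were not called, with adjusted p of 0.295, 0.797, 0.958 and 0.187. Of 14 genes of DNA and RNA sensing, 8 were higher and 1 lower (8 and 2 adjusted over the list alone). The median was 0.33 (adjusted p = 0.0235, and adjusted p = 0.92 with an estimated correlation, 0.0508 without Pfp/Rag2-/- library 2). Among them Samhd1, which breaks down nucleotides, differed by 1.01 on the log2 scale (SE 0.12).

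Genes of growth and stress were higher in GFP+ cells of WT hosts by small amounts. Of 33 cell cycle genes, 24 were higher and 1 lower (24 and 1 adjusted over the list alone). The median was 0.25 (adjusted p = 1.67e-07, and adjusted p = 0.589 with an estimated correlation). Top2a, which untangles replicated DNA, was at 16330 ± 1315 against 11920 ± 274.6 (log2 0.45, SE 0.07, adjusted p = 0.00417; 0.142 with all 18 libraries in 1 fit and 0.0604 with quantile normalization). The lower gene was Ccne2 (log2 -0.67, SE 0.12). Of 25 genes of hypoxia and glycolysis, 17 were higher and 0 lower (17 and 0 adjusted over the list alone, median 0.59, adjusted p = 4.22e-08, and adjusted p = 0.589 with an estimated correlation), with Car9 at 1.12 (SE 0.20) and Hk2 at 1.05 (SE 0.13) on the log2 scale. Of 13 heat shock genes, 9 were higher and 0 lower (9 and 0 adjusted over the list alone, median 0.47, adjusted p = 0.000433, and adjusted p = 0.662 with an estimated correlation), led by Hsph1 (log2 1.32, SE 0.17) and Bag3 (log2 1.32, SE 0.21). Of 24 genes of the unfolded protein and amino acid stress response, 10 were higher and 2 lower (11 and 3 adjusted over the list alone). The median was 0.28 (adjusted p = 0.00861, and adjusted p = 0.589 with an estimated correlation, 0.135 with quantile normalization). Phgdh, the entry enzyme of serine synthesis, was the highest of them (log2 0.54, SE 0.11).

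Genes of pericytes, fibroblasts and oligodendrocytes were lower in GFP+ cells of WT hosts. Of 15 genes of pericytes and fibroblasts 0 were higher and 7 lower (0 and 8 adjusted over the list alone). The median was -1.19 (adjusted p = 0.000999, and adjusted p = 0.92 with an estimated correlation). Dcn, a matrix proteoglycan, was at 2.502 ± 1.404 against 101.8 ± 18.01 (log2 -4.95, SE 0.39), and Col1a2, a collagen chain, at 27.87 ± 30.1 against 566.1 ± 552.2 (log2 -4.31, SE 0.90, adjusted p = 0.0129; 0.0529 without WT library 2). Of 13 genes of the oligodendrocyte lineage, 0 were higher and 7 lower (0 and 9 adjusted over the list alone, median -0.64, adjusted p = 0.00383, and adjusted p = 0.92 with an estimated correlation, 0.121 with fry), among them the myelin genes Mog (log2 -1.62, SE 0.25) and Cldn11 (log2 -1.38, SE 0.19). The endothelial list had 1 of 18 members higher and 0 lower (1 and 0 adjusted over the list alone). The median was -1.69 (adjusted p = 0.0107, and adjusted p = 0.92 with an estimated correlation, 0.341 with fry). It did not pass without Pfp/Rag2-/- library 1 (median -1.16, adjusted p = 0.0532) or without both libraries numbered 1 (median -0.58, adjusted p = 0.154). The called member, Ly6c1, was higher (log2 4.12, SE 0.52). Endothelial markers stood at 15% ± 14 of their GFP- level in WT and 43.4% ± 22.7 in Pfp/Rag2-/- hosts (15 markers; exact permutation p = 0.2 without pairing). By the median ratio they were lower in WT for each replicate number (4.51% against 69.5%, 9.62% against 28.5% and 31% against 32.1%). Oligodendrocyte markers stood at 12.2% ± 12.5 and 33.3% ± 9.99 (3 markers; exact permutation p = 0.2), or 33.9% and 48.9% with counts summed (p = 0.7). Of 31 genes of the extracellular matrix, 10 were higher and 11 lower (10 and 14 adjusted over the list alone, median -0.04, adjusted p = 0.764), with Fn1, fibronectin, higher (log2 2.29, SE 0.13) and Lox, which links collagen fibres, lower (log2 -3.48, SE 0.49).

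The highest log2 differences among all genes were those of Apol6, an apolipoprotein L family member (1109 ± 102.8 against 3.362 ± 1.393; log2 8.04, SE 0.27, adjusted p = 3.57e-05), H2-Eb2 (log2 7.47, SE 0.72), Gbp10 (7.36, SE 0.59), Ccl8 (6.81, SE 0.90), Ccl24 and Ubd (6.46, SE 0.36). Ccl24 had no read in the Pfp/Rag2-/- libraries and was at least 57.9-fold higher than the floor of 3 reads per library. The lowest were Slc6a3 (3 reads in WT against 102.5 ± 23.57 in Pfp/Rag2-/- hosts, ratio 111, interval 37.7 to 542), Dcn, Fhl1 (-4.73, SE 0.42), Col1a2, Pla2g2f (-4.00, SE 0.19) and Miat (-3.95, SE 0.57). Of the T cell genes measured (8), cytotoxic effectors (8) and NK cell genes (6), 0 were called by limma, with adjusted list p of 0.637, 0.89 and 0.811. The pan-macrophage list had 1 of 22 members higher and 0 lower (1 and 0 adjusted over the list alone, median 0.77, adjusted p = 0.0564). It passed with quantile normalization (0.0307), without WT library 2 (median 1.16, adjusted p = 0.00433), without Pfp/Rag2-/- library 1 (1.55, 1.78e-06) and without both libraries numbered 1 (1.05, 9.09e-08), and had a median of -0.04 with carry-over subtracted. The monocyte-derived macrophage list had 5 of 18 higher and 0 lower (5 and 0 adjusted over the list alone). The median was 0.31 (adjusted p = 0.165; 0.0289 without WT library 2, 0.0108 without Pfp/Rag2-/- library 1). Ptprc, the leukocyte marker CD45, was at 406.5 ± 471 against 648 ± 1036 and was not called.

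By limma, 2269 genes were higher and 2228 lower in GFP+ cells of WT hosts among 14807 tested, and 448 and 611 of these differed at least 2-fold. The gene list tests called 12 lists higher and 3 lower. With the replicate numbers as blocks, paired by correlation alone, 4588 genes were called. The macrophage (adjusted p = 0.000192), monocyte-derived macrophage (0.0229), NF-kB (0.00257) and mitochondrially encoded (0.0354) lists then passed as well. The 4497 calls fell to 2912 without WT library 1, 2691 without WT library 2, 2449 without Pfp/Rag2-/- library 2, 2597 without Pfp/Rag2-/- library 3, 2179 without both libraries numbered 1 and 2971 with all 18 libraries in 1 fit. With an estimated correlation 0 of the 40 lists passed in camera, with 2 at an unadjusted p under 0.05, and fry called 12.

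Unsorted WT tumours were compared with unsorted Pfp/Rag2-/- tumours to show the same host difference in tumour cells together with the cells around them. Lymphocyte genes were higher in WT tumours. Of 20 T cell genes, 17 were higher and 0 lower (17 and 0 adjusted over the list alone, median 3.03, adjusted p = 2.74e-09, and adjusted p = 0.17 with an estimated correlation), with Cd8a at 88.78 ± 48.58 against 2.095 ± 2.271 and Cd3d at 41.2 ± 23.56 against 0.3019 ± 0.523 (ratio 136, interval 24.1 to 5430). Of 11 cytotoxic effector genes, 9 were higher and 0 lower (9 and 0 adjusted over the list alone). The median was 2.55 (adjusted p = 7.75e-07, and adjusted p = 0.159 with an estimated correlation). Gzmb, a protease of killer cells, was at 666.5 ± 144.4 against 42.22 ± 7.143 (log2 3.94, SE 0.21, adjusted p = 7.55e-05). Ifng, the gene of interferon-gamma (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892), was at 34.52 ± 11.57 in WT tumours and had no read in Pfp/Rag2-/- tumours, at least 12.8-fold higher than the floor (adjusted p = 0.000307).

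Regulatory and exhausted T cell genes were higher in 8 of 12 and lower in 0 (11 and 0 adjusted over the list alone, median 1.87, adjusted p = 6.33e-06, and adjusted p = 0.201 with an estimated correlation), among them the checkpoint receptor Ctla4 (ratio 178, interval 31.6 to 7080) and Il2ra (log2 4.20, SE 0.40). NK cell genes were higher in 6 of 12 and lower in 0 (7 and 0 adjusted over the list alone, median 1.30, adjusted p = 4.29e-05, and adjusted p = 0.106 with an estimated correlation), with the receptor gene Klrk1 at 425 ± 86.62 against 28.46 ± 1.154. B and plasma cell genes were higher in 5 of 7 and lower in 0 (5 and 1 adjusted over the list alone, median 1.62, adjusted p = 0.0229, and adjusted p = 0.18 with an estimated correlation), with the antibody genes Igkc (log2 3.89, SE 0.57) and Jchain (log2 2.96, SE 0.40). The T cell list did not pass without WT unsorted library 1, 2 or 3 (adjusted p = 0.119, 0.0621 and 0.137), nor did the B cell list (0.638, 0.633 and 0.39). In these runs the filter drops genes found only in the group left with 2 libraries.

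Macrophage genes were higher in 21 of 22 and lower in 0 in unsorted WT tumours (22 and 0 adjusted over the list alone). The median was 1.62 (adjusted p = 2.2e-16, and adjusted p = 0.106 with an estimated correlation). Fcer1g, a receptor chain of myeloid cells, was at 956.6 ± 85.23 against 207 ± 20.21, and Adgre1, the marker F4/80, at 763.1 ± 134 against 180.2 ± 40.32. Macrophage markers stood at 6.39% ± 0.457 of their GFP- level in WT and 2.01% ± 0.237 in Pfp/Rag2-/- unsorted tumours. T cell markers stood at 2.95% ± 1.17 and 0.19% ± 0.0283, or 3.54% and 1.28% with counts summed (exact permutation p = 0.1 each, the smallest possible). Monocyte-derived macrophage genes were higher in 12 of 18 and lower in 1 (13 and 1 adjusted over the list alone). The median was 2.04 (adjusted p = 2.28e-06, and adjusted p = 0.106 with an estimated correlation). Mrc1, a scavenger receptor, differed by 3.98 on the log2 scale (SE 0.45), and the lower gene was Vcan (log2 -0.86, SE 0.15). Dendritic cell genes were higher in 7 of 13 and lower in 1 (10 and 1 adjusted over the list alone). The median was 0.99 (adjusted p = 0.00233, and adjusted p = 0.198 with an estimated correlation). Homeostatic microglia genes were higher in 5 of 13 and lower in 0 (6 and 1 adjusted over the list alone, median 0.35, adjusted p = 0.0233, and adjusted p = 0.435 with an estimated correlation), with Olfml3 at 3467 ± 551.8 against 833.8 ± 91.67. Neutrophil genes were higher in 3 of 5 and lower in 0 (3 and 0 adjusted over the list alone, median 1.41, adjusted p = 0.0413, and adjusted p = 0.201 with an estimated correlation, 0.173 without WT unsorted library 1), with Lcn2 at 536.2 ± 164.7 against 108.9 ± 46.58.

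The presentation and interferon-gamma genes were higher in unsorted WT tumours as well, beside these markers of immune cells. Of 22 class I genes 21 were higher and 0 lower (21 and 0 adjusted over the list alone, median 1.60, adjusted p = 2.39e-18, and adjusted p = 0.159 with an estimated correlation), and all 12 class II genes were higher (12 and 0 adjusted over the list alone). The median was 3.71 (adjusted p = 3.67e-12, and adjusted p = 0.159 with an estimated correlation). All 29 genes of the interferon-gamma response were higher (29 and 0 adjusted over the list alone). The median was 2.40 (adjusted p = 2.5e-27, and adjusted p = 0.106 with an estimated correlation). Psmb9 was at 4614 ± 73.28 against 635.9 ± 11.67, Cd74 at 27210 ± 7918 against 902.6 ± 238.4, and Cxcl9, a chemokine induced by interferon-gamma, at 765.4 ± 299.3 against 6.881 ± 1.312. Inhibitory ligands and immune evasion genes were higher in 19 of 33 and lower in 0 (21 and 0 adjusted over the list alone, median 0.85, adjusted p = 2.16e-08, and adjusted p = 0.106 with an estimated correlation), including Cd274 (log2 2.80, SE 0.15) and Pdcd1lg2, the other ligand of PD-1 (log2 4.90, SE 0.41). Chemokines were higher in 12 of 15 and lower in 0 (12 and 0 adjusted over the list alone). The median was 1.97 (adjusted p = 3.57e-07, and adjusted p = 0.106 with an estimated correlation). NF-kB targets were higher in 12 of 20 and lower in 0 (12 and 0 adjusted over the list alone, median 0.92, adjusted p = 2.84e-05, and adjusted p = 0.159 with an estimated correlation), with the cytokine Il1b at 269.2 ± 91.22 against 33.23 ± 7.619. Complement genes were higher in 13 of 17 and lower in 0 (13 and 1 adjusted over the list alone, median 1.65, adjusted p = 8.67e-09, and adjusted p = 0.159 with an estimated correlation), with C3 at 1719 ± 722.5 against 152.5 ± 32.61.

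Type I interferon-stimulated genes were lower as a group in unsorted WT tumours, with 4 of 30 higher and 15 lower (5 and 15 adjusted over the list alone). The median was -0.44 (adjusted p = 0.0166, and adjusted p = 0.548 with an estimated correlation, 0.152 without WT unsorted library 1). Oas2 was at 310.5 ± 32.54 against 1218 ± 214 (log2 -1.96, SE 0.15), and Ifit1 (log2 -1.07, SE 0.11) and Irf7 (log2 -1.03, SE 0.13) were also lower. DNA and RNA sensing genes were higher in 6 of 14 and lower in 2 (8 and 3 adjusted over the list alone, median 0.35, adjusted p = 0.0233, and adjusted p = 0.334 with an estimated correlation), with Ifi204 higher (log2 1.97, SE 0.11) and the RNA sensor Ddx58 lower (log2 -0.69, SE 0.14).

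Cell cycle genes were higher in 18 of 33 and lower in 0 (20 and 0 adjusted over the list alone, median 0.31, adjusted p = 2.28e-06, and adjusted p = 0.334 with an estimated correlation), with Mcm3 at 0.63 on the log2 scale (SE 0.09). Hypoxia and glycolysis genes were higher in 15 of 25 and lower in 0 (15 and 0 adjusted over the list alone, median 0.59, adjusted p = 2.28e-06, and adjusted p = 0.247 with an estimated correlation), with Hk2 at 1.04 (SE 0.18). Genes of oxidative phosphorylation were higher in 13 of 30 and lower in 0 (14 and 0 adjusted over the list alone, median 0.28, adjusted p = 7.69e-06, and adjusted p = 0.334 with an estimated correlation), heat shock genes in 5 of 12 and lower in 0 (6 and 1 adjusted over the list alone). The median was 0.40 (adjusted p = 0.00936, and adjusted p = 0.159 with an estimated correlation). The cholesterol list was higher with 1 of 22 members called higher, Ebp, and 0 lower (1 and 0 adjusted over the list alone). The median was 0.41 (adjusted p = 0.00658, and adjusted p = 0.66 with an estimated correlation, 0.342 with fry, 0.0586 without WT unsorted library 2). Oligodendrocyte genes were lower in 5 of 14 and higher in 0 (0 and 6 adjusted over the list alone, median -0.53, adjusted p = 0.00133, and adjusted p = 0.198 with an estimated correlation), with Myrf at -1.11 (SE 0.18) and Cldn11 at -0.91 (SE 0.14). Neuronal genes were lower as a group with 1 of 15 higher and 2 lower (1 and 6 adjusted over the list alone). The median was -1.41 (adjusted p = 0.0118, and adjusted p = 0.566 with an estimated correlation, 0.149 with fry, 0.0721 without WT unsorted library 1). Immediate-early genes were lower in 10 of 23 and higher in 1 (4 and 10 adjusted over the list alone). The median was -0.34 (adjusted p = 0.0233, and adjusted p = 0.566 with an estimated correlation, 0.0639 with fry). That list did not pass without WT unsorted library 2 (0.0621) or 3 (0.0803) or Pfp/Rag2-/- unsorted library 2 (0.0724).

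By limma, 2326 genes were higher and 2294 lower in unsorted WT tumours among 15448 tested, and 936 and 619 of these differed at least 2-fold. The highest log2 differences were those of Apol6 (9.52, SE 0.45), Arg1 (7.53, SE 0.61), Ubd (7.24, SE 0.36) and Ccl8 (6.65, SE 1.10), with H2-Eb2 (ratio 908, interval 251 to 7510) and Ccl24 (ratio 511, interval 141 to 4220), which had 2 reads each in Pfp/Rag2-/- tumours. The lowest were those of Pla2g2f (-3.53, SE 0.52), Pcdhb9 (-3.13, SE 0.41), Ramp1 (-3.08, SE 0.18), Gabra2 (-2.97, SE 0.63), Asic4 (-2.75, SE 0.53) and Cckar (-2.74, SE 0.36). Among 14333 genes tested in both fractions, 1092 were higher in WT in both, where independent calls would share 342, and 1086 were lower in both, where 339 would be shared. Another 33 were called in opposite directions. The 4620 calls fell to 2863 without WT unsorted library 3, and to 3049, 2275 and 2842 without Pfp/Rag2-/- unsorted library 1, 2 and 3. With an estimated correlation 0 of 27 called lists passed in camera, with 12 lists at an unadjusted p under 0.05, and fry called 24.

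**Figure D2:**
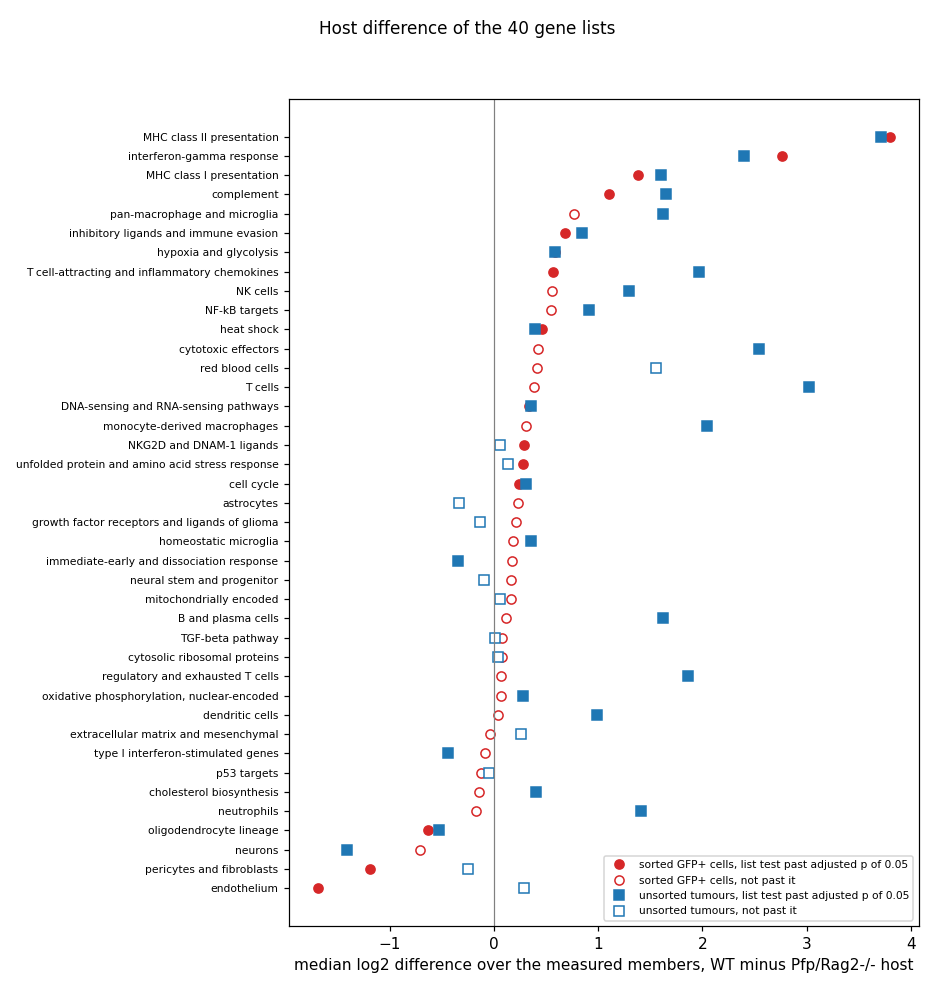
Median log2 difference, WT minus Pfp/Rag2-/- hosts, of the 40 gene lists. Red circles are sorted GFP+ cells and blue squares unsorted tumours, and filled symbols passed the list test at an adjusted p of 0.05 with the preset correlation. The interferon-gamma list lies at 2.77 in sorted cells and 2.40 in unsorted tumours.

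Unsorted tumours were compared with sorted GFP+ cells of the same host to separate what the other cells of a tumour add. Immediate-early genes, which respond quickly to growth signals and stress, were far lower in unsorted tumours of both hosts. In WT hosts 21 of 23 were lower and 0 higher (0 and 23 adjusted over the list alone). The median was -2.41 (adjusted p = 1.69e-22, and adjusted p = 0.671 with an estimated correlation). In Pfp/Rag2-/- hosts 20 of 23 were lower and 0 higher (0 and 21 adjusted over the list alone). The median was -1.94 (adjusted p = 9.81e-23, and adjusted p = 0.361 with an estimated correlation). Fosb, a subunit of the transcription factor AP-1 (ENSMUSG00000003545, chromosome 7, 19302696 to 19310051), was at 91.33 ± 7.998 in unsorted and 18730 ± 7547 in sorted WT cells (log2 -7.57, SE 0.31, adjusted p = 0.000209). In Pfp/Rag2-/- hosts it was at 176 ± 12.26 and 9115 ± 905.5 (log2 -5.68, SE 0.09, adjusted p = 4.31e-07). Fos (log2 -4.66, SE 0.17), Egr1 (-3.72, SE 0.19) and Jun (-2.65, SE 0.17) were lower in unsorted WT tumours, and Fos (-3.71, SE 0.07), Egr1 (-2.41, SE 0.11) and Jun (-2.10, SE 0.08) in unsorted Pfp/Rag2-/- tumours. Heat shock genes were lower in 5 of 13 and higher in 0 in WT (1 and 8 adjusted over the list alone, median -0.39, adjusted p = 0.00151, and adjusted p = 0.671 with an estimated correlation) and in 7 of 13 and higher in 0 in Pfp/Rag2-/- hosts (0 and 7 adjusted over the list alone). The median was -0.19 (adjusted p = 0.000494, and adjusted p = 0.361 with an estimated correlation).

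**Figure D3:**
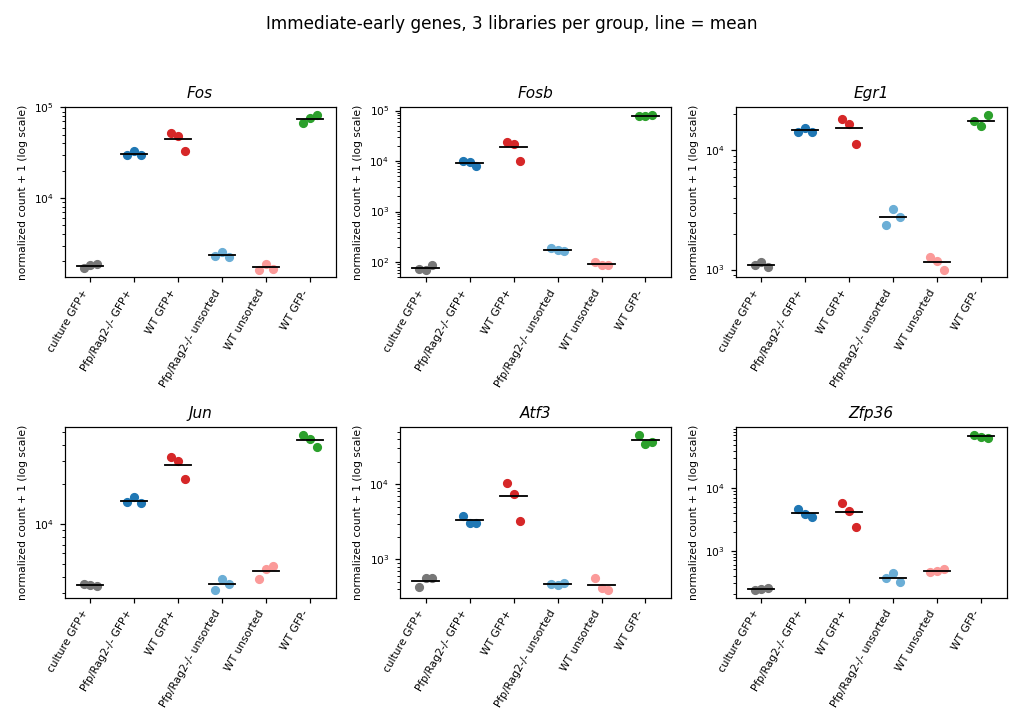
Normalized count plus 1 (log axis) of 6 immediate-early genes in each library of the 6 groups. Points are libraries and lines are group means. Fosb means are 18730 in sorted WT GFP+ cells, 91.33 in unsorted WT tumours and 76.12 in culture.

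Genes of other brain and vessel cells were higher in unsorted WT tumours than in GFP+ cells (adjusted p = 0.671 with an estimated correlation for each list named here). Neuronal genes were higher in 10 of 15 and lower in 1 (12 and 1 adjusted over the list alone). The median was 3.53 (adjusted p = 4.32e-05). Gad2, which makes the transmitter GABA, was at 168.5 ± 103.4 and had no read in GFP+ cells, at least 59.6-fold higher than the floor. Astrocyte genes were higher in 7 of 11 and lower in 0 (8 and 0 adjusted over the list alone, median 2.24, adjusted p = 0.000973), with the water channel Aqp4 at 510.6 ± 196.7 against 15.39 ± 23.38. Endothelial genes were higher in 15 of 18 and lower in 0 (17 and 0 adjusted over the list alone, median 2.79, adjusted p = 4.78e-08), with Kdr, a receptor of vascular growth factor, at 396 ± 114.6 against 44.66 ± 43.5. Pericyte and fibroblast genes were higher in 8 of 16 and lower in 1 (11 and 1 adjusted over the list alone). The median was 1.74 (adjusted p = 0.00888). Macrophage genes were higher in 18 of 22 and lower in 0 (21 and 0 adjusted over the list alone, median 2.18, adjusted p = 4.41e-10), with Cx3cr1 at 793.4 ± 236.7 against 98.22 ± 83.35. Homeostatic microglia genes were higher in 7 of 12 and lower in 0 (9 and 1 adjusted over the list alone, median 1.60, adjusted p = 0.000265), and class II genes in 4 of 12 and lower in 0 (9 and 0 adjusted over the list alone). The median was 0.87 (adjusted p = 0.0016). T cell genes passed as a list with 1 of 23 members higher and 0 lower (0 and 0 adjusted over the list alone). The median was 1.61 (adjusted p = 0.00282). Hypoxia and glycolysis genes were lower in 5 of 25 and higher in 1 (1 and 6 adjusted over the list alone, median -0.16, adjusted p = 0.00201), with Vegfa at 2791 ± 750.8 against 6281 ± 369.

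In this WT comparison limma called 1572 genes higher and 987 lower in unsorted tumours among 15275, and 1160 and 265 of these differed at least 2-fold. The 2559 calls fell to 6 without WT unsorted library 3 (356 with the gene set kept), 321 without WT unsorted library 2 (1321), 803 without WT GFP+ library 2 (841) and 1702 without WT GFP+ library 1, and to 1619 with a filter at 50, while 4430 passed with all 18 libraries in 1 fit. Without WT unsorted library 3, Aqp4 (adjusted p = 0.0932), Kdr (0.0932), Cx3cr1 (0.0943) and Vegfa (0.07) did not pass, and without library 2 they had adjusted p of 0.0594, 0.0604, 0.0604 and 0.053. By fry 8 of the 40 lists passed, and the endothelial (0.0528), pericyte and fibroblast (0.088), class II (0.0933) and T cell (0.288) lists did not.

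In Pfp/Rag2-/- hosts the same comparison gave neuronal genes higher in 11 of 15 and lower in 0 (13 and 0 adjusted over the list alone, median 3.42, adjusted p = 2.83e-05, and adjusted p = 0.979 with an estimated correlation, which holds for each list below). By fry no list of this paragraph passed (adjusted p = 0.0647 for neurons, 0.0752 for astrocytes, 0.238 for endothelium, 0.29 for macrophages, 0.0675 for mitochondrially encoded genes, 0.185 for hypoxia, 0.267 for cholesterol and 0.221 for matrix). Penk, a neuropeptide precursor, was at 586.1 ± 379.6 against 0.3044 ± 0.5272 (ratio 1930, interval 345 to 76100, adjusted p = 0.00024), and Gad1 differed by 5.93 (SE 0.73). Astrocyte genes were higher in 8 of 13 and lower in 0 (9 and 0 adjusted over the list alone, median 1.90, adjusted p = 0.0011), with Aqp4 at 4.26 (SE 0.47). Endothelial genes were higher in 5 of 18 and lower in 0 (13 and 0 adjusted over the list alone, median 0.98, adjusted p = 0.00378), and macrophage genes in 7 of 22 and lower in 0 (9 and 0 adjusted over the list alone). The median was 1.30 (adjusted p = 0.00802). Of 7 mitochondrially encoded genes 6 were higher and 0 lower (7 and 0 adjusted over the list alone, median 0.99, adjusted p = 0.00107), with mt-Nd5 at 18370 ± 4064 against 7757 ± 703.6. Hypoxia and glycolysis genes were lower in 12 of 25 and higher in 1 (1 and 13 adjusted over the list alone). The median was -0.27 (adjusted p = 0.000126). Cholesterol synthesis genes were lower in 8 of 22 and higher in 0 (0 and 12 adjusted over the list alone, median -0.36, adjusted p = 1.32e-05). Extracellular matrix genes were lower in 7 of 31 and higher in 3 (3 and 8 adjusted over the list alone, median -0.13, adjusted p = 0.0249; 0.0714 with quantile normalization), with Col6a2 at -1.46 (SE 0.12). By limma 2926 genes were higher and 1699 lower in unsorted tumours among 15324, and 1015 and 322 of these differed at least 2-fold. The 4625 calls fell to 2868 without Pfp/Rag2-/- GFP+ library 2, 2823 without GFP+ library 3, 2586 without unsorted library 2 and 2686 with all 18 libraries in 1 fit. The share of calls that were higher, 63.3%, was not kept with TMM (2248 higher, 2249 lower), edgeR (2136 and 2187) or DESeq2 (2288 and 2123).

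GFP- cells of WT tumours were compared with GFP+ cells of WT tumours to show what the sort separated. The series design speaks of tumours without GFP label as controls, whereas the sample labels, followed here, give sorted GFP- cells, and all GFP- levels and carry-over shares rest on these labels. GFP- cells carried the genes of immune cells and GFP+ cells those of dividing neural progenitors (adjusted p = 0.618 with an estimated correlation for each list named here except endothelium, at 0.654; counts adjusted over the list alone were the same). All 24 T cell genes were higher in GFP- cells (median 6.87, adjusted p = 2.04e-05), with Cd2 at 1753 ± 235.3 against 15.57 ± 21.48. All 22 macrophage genes were higher (median 6.19, adjusted p = 1.02e-06). Ptprc was at 30650 ± 1238 against 406.5 ± 471, and Ctss, a protease of antigen-presenting cells, at 149000 ± 24500 against 2228 ± 1285. NK cell genes were higher in 17 of 18 and lower in 0 (median 6.48, adjusted p = 0.000996), cytotoxic effectors in 14 of 15 and lower in 0 (median 6.82, adjusted p = 0.00343), B and plasma cell genes in 14 of 16 and lower in 2 (median 5.34, adjusted p = 0.00239), and class II genes in 12 of 12 (median 4.16, adjusted p = 7.1e-05). Endothelial genes were higher in 17 of 18 and lower in 1 (median 2.89, adjusted p = 0.0143). The 2 lower B cell genes were Cr2 (log2 -4.20, SE 0.70) and Pax5 (log2 -2.17, SE 0.29).

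Type I interferon-stimulated genes were higher in GFP- cells in 21 of 30 and lower in 5 (median 1.13, adjusted p = 0.00645, and adjusted p = 0.618 with an estimated correlation, as for each list called in this paragraph), with Mx1 at 3933 ± 542.3 against 192.5 ± 42.29. Inhibitory ligands and immune evasion genes were higher in 27 of 33 and lower in 4 (median 2.86, adjusted p = 0.000897), with Ptgs2, which makes prostaglandins, at 36390 ± 19550 against 318.5 ± 391.2. Immediate-early genes were higher in 19 of 23 and lower in 1, Myc (median 2.21, adjusted p = 0.00181). Class I genes, higher in 12 of 22 and lower in 2 (median 0.35, adjusted p = 0.182), and interferon-gamma genes, higher in 11 of 29 and lower in 13 (median -0.25, adjusted p = 0.226), did not pass by camera, while class I genes passed by fry (adjusted p = 0.00464). Cell cycle genes were lower in GFP- cells in 29 of 33 and higher in 1 (median -1.57, adjusted p = 1.02e-06), with Cdc20 at 649.8 ± 378.6 against 5675 ± 171.6. The higher gene, Pcna (log2 0.24, adjusted p = 0.0309), turned to -0.35 with quantile normalization. Neural stem and progenitor genes were lower in 12 of 16 and higher in 4 (median -2.01, adjusted p = 0.0143), with Sox2 at 356.9 ± 392.4 against 6186 ± 753.4 and Olig2 at 472.4 ± 534.1 against 7571 ± 1717. Ligands of NKG2D and DNAM-1 were lower in 5 of 6 and higher in 0 (median -2.17, adjusted p = 0.0216), with Raet1e at 34.36 ± 31.25 against 619.9 ± 23.36. By limma 6871 genes were higher and 5412 lower among 16083, and 5080 and 3593 of these differed at least 2-fold. The median log2 difference of all genes was 0.19 with the authors' factors, 0.07 with TMM and -0.22 with quantile normalization, under which 5401 were higher and 7033 lower.

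**Figure D4:**
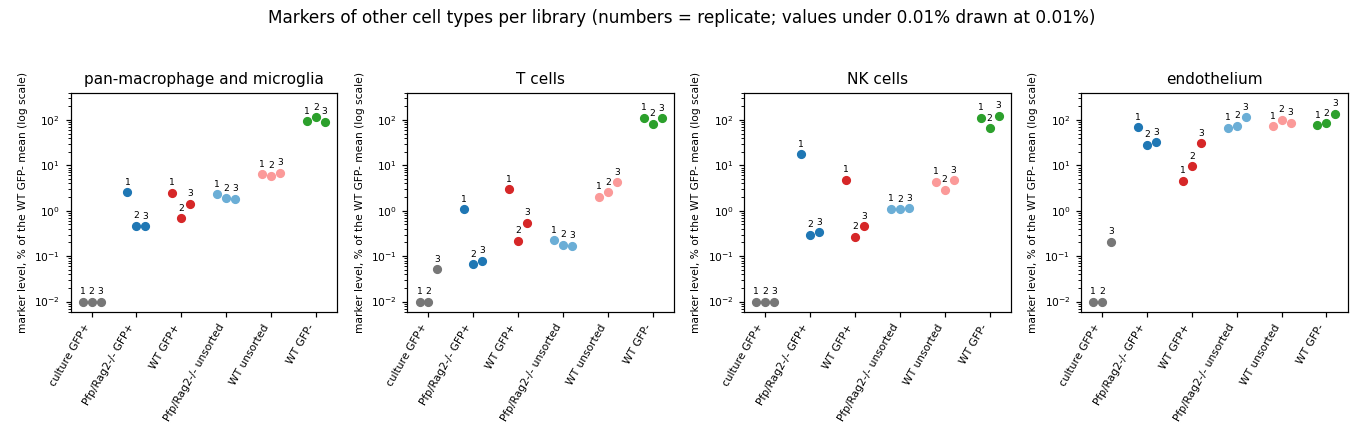
Level of macrophage, T cell, NK cell and endothelial markers in each library as a percent of their mean in WT GFP- cells (log axis, values under 0.01% drawn at 0.01%, digits are replicate numbers). NK cell markers reach 17.6% in GFP+ library 1 of Pfp/Rag2-/- hosts and 4.85% in GFP+ library 1 of WT hosts.

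GFP+ cells grown in each host were compared with the cultured cells used for injection to show what differed after growth in the brain and recovery from the tumour. In WT hosts all 29 interferon-gamma genes (median 3.06, adjusted p = 1.36e-14) and all 10 measured class II genes (median 8.56, adjusted p = 4.67e-08) were higher, and class I genes were higher in 19 of 22 and lower in 3 (median 2.30, adjusted p = 6.92e-10). The adjusted p of these 3 lists was 0.463 with an estimated correlation, and the counts adjusted over the list alone were the same. H2-Eb1, a class II chain, was at 9296 ± 1487 against 0.6284 ± 1.088 (ratio 14800, interval 4090 to 122000, adjusted p = 7.54e-08). B2m was at 30780 ± 2237 against 14500 ± 409 (log2 1.08, SE 0.06). In Pfp/Rag2-/- hosts interferon-gamma genes were higher in 9 of 26 and lower in 12 (9 and 13 adjusted over the list alone, median -0.20, adjusted p = 0.786), and class I genes higher in 14 of 22 and lower in 4 (14 and 4 adjusted over the list alone). The median was 0.62 (adjusted p = 0.0507). Class II genes there were higher in 7 of 9 and lower in 0 (7 and 0 adjusted over the list alone). The median was 4.57 (adjusted p = 0.0415, and adjusted p = 0.766 with an estimated correlation, 0.0554 with quantile normalization).

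Immediate-early genes were higher than in culture in both hosts, in 18 of 23 and lower in 0 in WT (18 and 0 adjusted over the list alone, median 2.21, adjusted p = 1.61e-07, and adjusted p = 0.486 with an estimated correlation) and in 17 of 23 and lower in 3 in Pfp/Rag2-/- hosts (17 and 3 adjusted over the list alone). The median was 1.79 (adjusted p = 7.25e-07, and adjusted p = 0.689 with an estimated correlation). Fosb rose from 76.12 ± 9.315 in culture to 18730 ± 7547 and 9115 ± 905.5. Cholesterol synthesis genes fell in 21 of 22 and rose in 0 in each host (0 and 21 adjusted over the list alone), with medians of -1.04 (adjusted p = 2.87e-06, and adjusted p = 0.486 with an estimated correlation) and -0.90 (adjusted p = 8.02e-05, and adjusted p = 0.732 with an estimated correlation). Stard4, which carries cholesterol, was at 682.1 ± 165.6 and 737.1 ± 103.8 against 2210 ± 170.9. Cell cycle genes were lower in 23 of 33 and higher in 3 in WT (3 and 23 adjusted over the list alone, median -0.39, adjusted p = 0.000236, and adjusted p = 0.483 with an estimated correlation) and lower in 29 and higher in 2 in Pfp/Rag2-/- hosts (2 and 29 adjusted over the list alone). The median was -0.70 (adjusted p = 7.25e-07, and adjusted p = 0.689 with an estimated correlation). Ribosomal protein genes were higher in 25 of 28 and lower in 1 in WT (25 and 1 adjusted over the list alone, median 0.37, adjusted p = 4.9e-07, and adjusted p = 0.486 with an estimated correlation) and higher in 22 and lower in 1 in Pfp/Rag2-/- hosts (22 and 1 adjusted over the list alone). The median was 0.31 (adjusted p = 9.68e-05, and adjusted p = 0.689 with an estimated correlation). Extracellular matrix genes were lower in 18 of 29 and higher in 9 in WT hosts (9 and 19 adjusted over the list alone, median -0.71, adjusted p = 0.0327, and adjusted p = 0.467 with an estimated correlation), with Col6a2 at 112.2 ± 6.711 against 3096 ± 65.98 and Col5a1 at 209.4 ± 16.29 against 3231 ± 62.6.

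Markers of other cell types were higher than in culture in the same libraries. Macrophage genes were higher in 21 of 22 and lower in 1 in WT hosts (21 and 1 adjusted over the list alone, median 6.58, or 6.32 with genes at 0 in culture at their bound; adjusted p = 2.48e-09, and adjusted p = 0.483 with an estimated correlation). In Pfp/Rag2-/- hosts they were higher in 20 and lower in 1 (20 and 1 adjusted over the list alone, median 5.96, at the bound 5.68; adjusted p = 2.76e-05, and adjusted p = 0.732 with an estimated correlation). Endothelial genes were higher in 16 of 18 and lower in 2 in Pfp/Rag2-/- hosts (16 and 2 adjusted over the list alone, median 4.40, at the bound 3.94; adjusted p = 0.000175, and adjusted p = 0.732 with an estimated correlation), and pericyte and fibroblast genes in 11 of 15 and lower in 2 (11 and 2 adjusted over the list alone). The median was 2.47 (adjusted p = 0.00672, and adjusted p = 0.724 with an estimated correlation). Complement genes were higher in 14 of 16 and lower in 2 in WT hosts (14 and 2 adjusted over the list alone, median 4.43, at the bound 4.12; adjusted p = 4.9e-07, and adjusted p = 0.296 with an estimated correlation) and in 11 of 13 and lower in 2 in Pfp/Rag2-/- hosts (11 and 2 adjusted over the list alone). The median was 2.32 (adjusted p = 0.00518, and adjusted p = 0.689 with an estimated correlation). C1qb, a starter of the complement cascade made by macrophages, had no read in culture and was at least 349-fold higher in WT and at least 219-fold higher in Pfp/Rag2-/- GFP+ cells. Chemokines were higher in 13 of 14 and lower in 0 in WT hosts (13 and 0 adjusted over the list alone, median 4.08, at the bound 3.56; adjusted p = 2.71e-05, and adjusted p = 0.483 with an estimated correlation), and hypoxia and glycolysis genes in 16 of 25 and lower in 3 (16 and 3 adjusted over the list alone). The median was 0.34 (adjusted p = 0.00049, and adjusted p = 0.486 with an estimated correlation).

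The largest differences from culture in WT hosts after H2-Eb1 were H2-Aa (log2 10.79, SE 0.23), Ctss (ratio 7010, interval 1260 to 277000) and Cd74 (log2 10.46, SE 0.23). The lowest were Rasgef1c (-5.82, SE 0.46), Wfdc1 (-5.73, SE 0.27), Gfra2 (-5.71, SE 0.17) and Efhd1 (-5.35, SE 0.26). In Pfp/Rag2-/- hosts Brinp3, Pid1 and Mobp had no read in culture and were at least 448-fold, 253-fold and 250-fold higher. Ctss was higher by a ratio of 3910 (interval 702 to 155000). Ly6c1 (log2 -6.04, SE 0.46), Chrdl2 (-5.97, SE 0.45), Crabp1 (-5.87, SE 0.23) and Rasgef1c (-5.38, SE 0.25) were lowest. By limma 4324 genes were higher and 5037 lower in WT hosts among 14261, and 5089 higher and 5377 lower in Pfp/Rag2-/- hosts among 14487. More genes were higher than lower with TMM (4742 and 4536 in WT, 5496 and 5033 in Pfp/Rag2-/- hosts), edgeR (4738 and 4475, 5448 and 4982) and DESeq2 (4418 and 4156, 4744 and 4690), so the balance depends on the setting. Differences of at least 2-fold numbered 1826 and 1195 in WT and 2228 and 1230 in Pfp/Rag2-/- hosts. Among 13988 genes tested in both, 3302 were higher in both hosts, where independent calls would share 1377, and 4131 were lower in both, where 1936 would be shared. In 50 simulations with the same cultured libraries and no true change, 0 genes were shared by limma, the tool used throughout. Across genes, which are not independent replicates, the log2 differences had r = 0.898 (0.272 simulated) and a covariance of 1.49 (0.0137 simulated). The 3 cultured libraries cannot be split between the comparisons, so part of the excess may come from the shared controls.

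Whether the host difference itself differed between sorted and unsorted cells was tested as an interaction. By limma 151 of 16161 genes passed, 115 with a higher and 36 with a lower WT difference in sorted cells, and 3212 had an unadjusted p under 0.05. Fhl1, a protein of muscle and motile cells, was lower in WT by more in sorted cells (log2 -4.73, SE 0.42) than in unsorted tumours (-1.63), a difference of -3.10 (SE 0.51, adjusted p = 0.0272). Fosb differed by 1.89 between the fractions (adjusted p = 0.0394) and Egr1 by 1.31 (adjusted p = 0.0381). The count depended on single libraries. It was 0 without Pfp/Rag2-/- GFP+ library 1 (with 2658 genes at an unadjusted p under 0.05), 1 without WT GFP+ library 1 or 2, without Pfp/Rag2-/- GFP+ library 3 or without Pfp/Rag2-/- unsorted library 1, 2 or 3, 3 without WT unsorted library 3, 40 without Pfp/Rag2-/- GFP+ library 2, 542 and 1108 without WT unsorted libraries 2 and 1, and 759 without WT GFP+ library 3. The edgeR and DESeq2 counts were 70 and 1216.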

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

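The tests of explanations in this part were chosen after the results were seen, while the counts over other splits of the libraries were planned.

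The host difference differed between sorted and unsorted cells for 151 genes by the test of the difference itself. Fhl1 differed by -3.10 (-4.73 sorted, -1.63 unsorted; adjusted p = 0.0272), Col6a2, a collagen chain, by -1.22 (-3.02 and -1.79; adjusted p = 0.0264), Fosb by 1.89 (0.95, adjusted p = 0.0565, and -0.94, adjusted p = 0.0042) and Egr1 by 1.31 (0.05 and -1.26; adjusted p = 0.0381). Lists with a lower WT difference in sorted cells, as median log2 values, were T cells (-2.27, adjusted p = 0.000736), regulatory and exhausted T cells (-1.48, 0.0268), cytotoxic effectors (-2.40, 0.0214), macrophages and microglia (-0.90, 0.0233), endothelium (-1.82, 6.16e-05), pericytes and fibroblasts (-1.25, 0.00152), cholesterol synthesis (-0.46, 0.000233) and oxidative phosphorylation (-0.22, 1.18e-05). Lists with a higher one were the interferon-gamma response (0.365, adjusted p = 0.0268), type I interferon-stimulated genes (0.241, 0.0402) and immediate-early genes (0.765, 6.16e-05). With an estimated correlation the adjusted p was 0.805 for each, and with fry 0.657, or 0.624 for oxidative phosphorylation. The interferon-gamma list also did not pass with quantile normalization (adjusted p = 0.353), nor did the type I list (0.0868, and 0.0532 with the replicate block). Of 100 drawn splits of the 12 libraries, the real one included, 4 called as many genes. The other 3 (762, 456 and 358 genes) put 5 of the 6 libraries of 1 sort or 1 host on 1 side, which points to a structure of the samples, although further splits of this kind called 0 to 11 by limma. Drawn splits mix the host and sort differences into the contrast and the spread, so they do not decide whether chance can be excluded. Without both GFP+ libraries numbered 1 the real count by limma was 0, with 2437 genes at an unadjusted p under 0.05.

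The comparisons of 3 against 3 libraries have 10 splits each, too few for a share under 0.05, and in each only 1 split, the real one, reached its own count. Against real counts of 4497, 2559, 4625, 12283, 9361 and 10466 the highest other split called 0 genes by limma (no other tool was run on the splits), with at most 762, 1236, 610, 126, 121 and 51 at an unadjusted p under 0.05. These are the host comparison of GFP+ cells, unsorted against GFP+ cells in WT and in Pfp/Rag2-/- hosts, GFP- against GFP+ cells, and the WT and Pfp/Rag2-/- cells against culture. For the unsorted host comparison, with 4620 genes, the highest other called 1, and at most 638 stood at an unadjusted p under 0.05. In the host comparison of GFP+ cells, where replicate numbers were treated as pairs, the other splits that part all 3 pairs also called 0, with 358, 62 and 83 genes at an unadjusted p under 0.05.

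Interferon-gamma response and class I genes were higher in GFP+ cells of WT hosts. If immune cells of both hosts express them alike (not measured), immune carry-over is argued against. The share difference (0.539%) gives a median of 0.776% of the host difference of the 46 called genes, at most 27.2% (Cxcl9). After subtraction 45 were still called higher. Class II stays open (median 4.9%, 1.43% to 10.9%): 6 of 6 stayed called, but subtraction exceeded Cd74 in each Pfp/Rag2-/- library. The authors' scaling is argued against by a median of 2.69 for the interferon-gamma list with quantile normalization. Interferon-gamma from lymphocytes of WT hosts stays open. Ifng was at least 12.8-fold higher in unsorted WT tumours than the floor of 3 reads (fitted log2 5.09, adjusted p = 0.000307). All 3 WT libraries lay above all 3 others, but Pfp/Rag2-/- GFP+ library 1 held it too (148.9).

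Immediate-early genes were higher in sorted GFP+ cells than in unsorted tumours. Sorting alone is argued against, since sorted cells from WT tumours exceeded the cultured cells, which per the labels were sorted too, by a median log2 of 2.21. In WT hosts the unsorted level lay between both sorted fractions for 2 of 23 genes and below both for 21. Astrocyte genes lay above both (median 2.24 over GFP+, GFP- at -1.105), so unsorted tumours were no mixture of both alone. Other cell types and a true difference stay open. So do digestion and handling, as the labels do not say whether unsorted cells were handled alike.

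Pericyte and fibroblast genes were lower in GFP+ cells of WT hosts, and endothelial genes had a median of -1.69 with 0 of 18 called lower. For pericyte and fibroblast genes library 1 alone is argued against, since their median was -0.92 without both libraries numbered 1 (adjusted p = 0.00934, and 0.000184 to 0.92 over all alternatives). Stromal cells in the sort and expression by tumour cells cannot be told apart for them: the 7 called genes stood at a median of 117% of the unsorted level in Pfp/Rag2-/- GFP+ cells (26.1% to 390%, 5 above 100%), the highest being Col1a2, at 1194, 345.4 and 158.4 in libraries 1, 2 and 3. Cultured cells held Cspg4 at 3068, Col1a1 at 2224 and Col3a1 at 2699, but Col1a2 at 1.891, Dcn at 0.6329 and Rgs5 at 0.3149. For endothelium, vascular cells sorted into Pfp/Rag2-/- GFP+ library 1 stay open, since the median without it was -1.16, and marker shares were 69.5%, 28.5% and 32.1% against 4.51%, 9.62% and 31% in WT libraries.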

How the results depend on the processing

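The tests without both GFP+ libraries numbered 1, with carry-over subtracted, and with 1 library left out but the gene set kept were chosen after results were seen, and the other alternatives were planned and were run. Of 5264 values for 332 results of single genes picked by rule or for the text, 4919 kept direction and call, 317 lost the call, 8 gained it and 20 changed direction. At the depth given above 3 reads stand for 2.61 to 4.62 in normalized values, which limits statements on genes near that level. Where a count changed, the cause was not tested, apart from fewer genes under a stricter filter and fewer libraries.

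For GFP+ cells between hosts, 4497 calls became 2971 with all 18 libraries in 1 fit, 2179 without both libraries numbered 1 and 4873 with carry-over subtracted. With 1 library left out they ranged from 2449 to 5532. The 4620 calls between unsorted tumours ranged from 2275 to 6142. For unsorted against GFP+ cells in WT hosts, 2559 became 1619 with at least 50 in 3 libraries and 4430 with all 18 libraries, and ranged from 6 (without WT unsorted library 3) to 3323. For the same comparison in Pfp/Rag2-/- hosts, 4625 became 2686 with all 18 libraries and ranged from 2586 to 4764. GFP- against GFP+ cells ranged from 10152 to 12542, and WT and Pfp/Rag2-/- GFP+ cells against culture from 7967 to 9723 and from 9193 to 10483. Calls against culture shared by both hosts fell to 2151 where a 2-fold change was asked for.

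The 151 genes whose host difference differed between sorted and unsorted cells became 61 without a filter, 298 with at least 50 in 3 libraries, 270 with quantile normalization, 76 with TMM, 34 with all 18 libraries, 70 with edgeR and 1216 with DESeq2. With 1 library left out they ranged from 0 to 1108. They were 0 by limma without Pfp/Rag2-/- GFP+ library 1 (2658 at an unadjusted p under 0.05), without Pfp/Rag2-/- unsorted library 2 with the gene set kept (2642) and without both GFP+ libraries numbered 1 (2437). No other tool was run on these subsets.

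GFP+ libraries of both hosts met the pair rule (lowest r 0.102), and the block gave 4588 genes. Elsewhere the rule was not met, and the block gave 3551 for unsorted tumours, 1864 and 3820 for unsorted against GFP+ cells in WT and Pfp/Rag2-/- hosts, 12242 for GFP- cells, 9107 and 10402 against culture, and 133 for the difference of host differences.

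The balance of higher and lower genes moved with scaling. With quantile normalization 1366 were higher and 1448 lower in unsorted than GFP+ cells of WT hosts, 2276 and 2352 in Pfp/Rag2-/- hosts, and 5401 and 7033 in GFP- cells. TMM gave, in Pfp/Rag2-/- hosts, 2248 and 2249, edgeR 2136 and 2187, and DESeq2 2288 and 2123. Against culture the lower genes were the majority, but the higher ones were with TMM, edgeR, DESeq2, no filter (5453 and 5029 in WT, 6328 and 5431 in Pfp/Rag2-/- hosts) and all 18 libraries (4435 and 3886, 4993 and 4077). Between unsorted tumours edgeR gave 2575 higher and 1952 lower.

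With the correlation between genes estimated, camera called 0 lists in all 8 tests, with 2, 12, 0, 2, 0, 4, 1 and 0 lists at an unadjusted p under 0.05, where the preset correlation had called 15, 27, 17, 11, 23, 18, 9 and 11. The order is GFP+ cells between hosts, unsorted tumours between hosts, unsorted against GFP+ cells in WT and in Pfp/Rag2-/- hosts, GFP- cells, WT and Pfp/Rag2-/- cells against culture, and the difference of host differences. By fry the counts were 12, 24, 8, 2, 30, 29, 27 and 0 (1 at an unadjusted p under 0.05). Quantile normalization gave 19 lists for the last. NK cell genes against culture in Pfp/Rag2-/- cells passed by fry as lower (adjusted p = 0.0493), against their median of 3.04, with 2 of 3 genes higher and Itga2 at -3.16.

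Directions changed for these genes. Between hosts in GFP+ cells, with 1 library left out, Prf1 ranged from -0.50 to 1.68, Ptprc from -0.43 to 2.28, Ifit3 from -0.137 to 0.038 and Mx1 from -0.46 to 0.53. Ptprc was at -0.66 with edgeR and DESeq2, Ifit3 at 0.093 and Mx1 at 0.38 without both libraries numbered 1, and Mx1 at 0.04 with quantile normalization. Between unsorted and GFP+ cells of Pfp/Rag2-/- hosts, Prf1 was at -0.34 with log2 of value plus 10, -0.80 with quantile normalization and -1.78 with edgeR, and ranged from -1.13 to 0.48. Pcna in GFP- against GFP+ cells was at -0.35 with quantile normalization.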

Other observations

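The list tests named here were planned, while the single genes and libraries were picked after their values were seen.

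By camera the following lists did not pass between GFP+ cells of the 2 hosts. Of 17 growth factor receptors and ligands of glioma 6 were higher and 3 lower in WT hosts (7 and 3 adjusted over the list alone, median 0.21, adjusted p = 0.476), although their mean, -0.16, has the other sign. Of 17 genes of the TGF-beta pathway 7 were higher and 2 lower (7 and 3 adjusted over the list alone, median 0.08, adjusted p = 0.388). Among 18 p53 targets 5 were higher and 4 lower (6 and 4 adjusted over the list alone, median -0.13, adjusted p = 0.764), and among 15 genes of neural stem and progenitor cells 3 were higher and 3 lower (median 0.17, adjusted p = 0.388, and 0.0154 with fry). Of 10 astrocyte genes 4 were higher and 1 lower (median 0.24, adjusted p = 0.294, and 0.0356 with fry), although their mean, -0.44, has the other sign, and of 10 neuronal genes 1 was higher and 1 lower (median -0.71, adjusted p = 0.481). For 6 genes of red blood cells 0 were called (median 0.42, adjusted p = 0.627). TGF-beta genes were higher in 13 of 18 in GFP- than in GFP+ cells of WT tumours and lower in 3 (median 1.70, adjusted p = 0.0496, and 0.618 with an estimated correlation).

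Single tumour genes moved between culture and host. Olig1, a transcription factor of the oligodendrocyte lineage, was at 10510, 12190 and 12190 in culture, 17410, 17710 and 24650 in GFP+ cells of WT hosts, and 27980, 31000 and 26830 in those of Pfp/Rag2-/- hosts. Nes, which encodes nestin, was at 17060, 14930 and 14240 in culture and at 5551, 5900 and 5970 in GFP+ cells of WT hosts.

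Pfp/Rag2-/- GFP+ library 1 held NK cell genes (Ncr1 54.79, Klrb1c 147.9, Gzma 1018) with little of the T cell gene Trac (7.306), whereas WT GFP+ library 1 held Trac at 76.62 and Ncr1 at 14.37. Tmem119, a microglia gene, was at 3063 to 7288 in the 6 GFP+ libraries from tumours and at 97.31 to 108.4 in culture. In unsorted WT tumours it was at 2598 in library 1 and at 13640 and 14210 in libraries 2 and 3.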
